A study of Mus musculus with 4 samples.

How the data were processed

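Mouse lung cells were sorted and sequenced with the 10x 3' single-cell protocol, per the labels' protocols, from mice of a mixed FVB/C57BL6 background that carried Sftpc-CreER, a Rosa26 green reporter and a red Hopx reporter and had received tamoxifen. The labels describe AT1 cells at 3 ages and AT2 cells at P60, which gives 4 samples in 4 groups with 1 library each. Dissociation differed between the cell types, since AT1 lungs were digested with neutral protease, elastase, type I collagenase and DNase I and AT2 lungs with neutral protease and DNase I only, per the labels' protocols. Dead cells were marked with DAPI. How many animals went into a library is not given in the sources used here.

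Each deposited file holds natural log values per gene and cell, which the authors made by scaling the UMIs of a cell to a sum of 10000, adding 1 and taking the logarithm, as the values themselves show. Cell Ranger 1.3.1 and Seurat 2.0.0 are named per the submitters' processing notes, together with the builds mm10 and hg19. The listed genes are mouse genes, and the role of hg19 is not given in the sources used here. The values were unlogged and divided by the smallest step of each cell, which gave whole UMIs for 100% of the values above 0 within a tolerance of 0.05. All counting below was done on these recovered UMIs. The analysis plan had foreseen log values and this recovery.

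The files had been filtered before deposit. The fewest cells per detected gene were 1 at P3, 6 at P15, 7 in the P60 AT1 library and 5 in the AT2 library, the highest mitochondrial shares of a cell were 8.95, 10, 9.94 and 15%, and 13992, 12851, 11561 and 12509 genes were listed. The AT2 file lists all 11561 genes of the P60 AT1 file plus 948 of its own, and a gene at 0 in every AT2 cell may have been filled in when tables were merged, so such a gene was described as listed at 0 and given no fold. A gene absent from a file was called not listed and was not taken as 0. No cell was removed from a library by UMIs or genes before clustering. A cluster of low UMI count was kept out of the AT2-like class, and thinning left out shallow cells. No reporter gene was used here.

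Each library was clustered alone in Scanpy 1.11.5 with igraph 0.11.9, on 2000 highly variable genes, 20 principal components, 15 nearest neighbours and Leiden resolution 0.5, with 0.25 and 1 as alternatives. Clusters were named from 13 marker lists, with leading genes ranked by fold with a prior of 20 CPM. A cluster took another name when 2 or more markers of another class were among its 10 leading genes and its level of the sorted type's markers was under 50% of the library median, and the sorted type's name needed 10 of its markers detected in 25% of the cells. A cluster of low UMI count stayed unnamed. Cells with 3 or more endothelial, lymphatic endothelial, fibroblast, pericyte or smooth muscle, immune or platelet markers, 4 mesothelial markers or 5 club or ciliated markers were set aside from the class. These naming thresholds and the platelet list were set after the data were seen. They kept out 43, 19 and 19 cells of the AT1-like clusters at P3, P15 and P60 (1.37, 0.646 and 1.42%), 30 cells of the AT2-like clusters (1.43%) and the unnamed AT2 cluster of 34 cells (1.62%). Scrublet marked 1, 1, 2 and 13 cells as doublets (0.0318, 0.034, 0.15 and 0.621%), too few to call it effective, so doublets between similar cells may remain and no cell was removed on its call.

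UMIs were summed over the class per library and expressed as CPM of all listed genes. For each of 4 comparisons the ratio of CPM was given with an exact conditional Poisson interval at 95%, single levels with exact Poisson intervals and shares of cells with exact Clopper-Pearson intervals, all of which cover counting error only. Genes needed 50 CPM and 30 UMIs in the higher library, and those at least 2-fold apart were counted by size. A count of 0 was set to a floor of 3 counts for these counts and for list medians, and a share of 0 was given the limit that 3 counts of the total allow. The medians of log2 ratios of 29 gene lists were set among 10000 random lists of the same size drawn within 20 bins of mean expression, and the percentile describes these libraries only. A list member counted as measured with 30 UMIs over both libraries, and a list needed 5 such members. The ribosomal protein list was made by gene symbol and also takes in a few Rps6k kinase genes and listed pseudogenes. Shares of cells with an Igfbp2 UMI, the split by Igfbp2 and cells with cell cycle genes were taken after thinning each cell to 2000 UMIs at random, leaving out shallower cells. Coordinates come from the GENCODE annotation of the mm10 assembly.

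Genes were named by a rule. It takes the 12 largest ratios in each direction among genes with 100 CPM in the higher library and the same direction when all cells are summed, without ribosomal protein, mitochondrial, haemoglobin and provisional gene symbols, then up to 4 examples per list at 20 CPM or more, and Igfbp2, Hopx, Pdpn, Ager, Aqp5 and Sftpc in every comparison. For the split by Igfbp2 it takes the 8 largest ratios in each direction. Scgb1a1, a gene of club cells, the immune cell genes Tyrobp and Cd52, Hba-a1 and Malat1 were chosen after their values were seen. The groups, comparisons, markers, lists, naming rule and 50 alternatives were fixed before the data were examined, and 17 alternatives were added afterwards.

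The counting step was tested on simulated data with known answers, drawn from the real means and library sizes with 200 genes changed, all at 100 CPM or more. In each of the 4 comparisons it recovered 100 of 100 genes changed 2.5-fold and 100 of 100 changed 4-fold. It called 0 of the unchanged genes past the minimum, which numbered 2668 for P60 over P3, 2648 for P15 over P3, 2908 for P60 over P15 and 3008 for AT2 over AT1, and the intervals covered the true ratio for 95.2, 95, 94.9 and 94.8% of genes. The simulation holds counting error only, with no spread between animals and no shift of composition between libraries. Its outcome was therefore nearly fixed in advance, and it checks the counting step alone. The alternatives covered other scalings, expression minimums, thinning depths, cluster resolutions, all cells in place of the class, and cells or clusters left out. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.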

Results

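Alveolar type I (AT1) cells are the flat epithelial cells that cover most of the gas exchange surface of the lung, and alveolar type II (AT2) cells are the cuboidal neighbours that make surfactant. Single-cell RNA libraries were made with the 10x 3' chemistry, which counts transcripts by unique molecular identifiers (UMIs), from sorted mouse lung cells of 4 groups with 1 library each. AT1 cells were sorted at postnatal day 3 (P3), day 15 (P15) and day 60 (P60) as cells carrying the red Hopx reporter and surface Pdpn but neither the green Sftpc lineage label nor CD45, and AT2 cells were sorted at P60 as cells with the green label and no CD45. The P3 library held 3149 cells with 26536894 UMIs, a median of 7477 UMIs per cell (range 3081 to 24969) and a median of 2537 detected genes. The P15 library held 2940 cells with 15401939 UMIs, a median of 4928 (1434 to 24119) and 2021 genes. The P60 AT1 library held 1337 cells with 7276458 UMIs, a median of 5279 (1121 to 23064) and 2143 genes. The AT2 library held 2093 cells with 10379705 UMIs, a median of 4864 (941 to 13446) and 1550 genes. With 1 library per group no difference below has a replicate check, so no test was made. Ranges in parentheses after folds and shares are exact 95% intervals that cover counting error only, and genes are counted by the size of their ratio alone.

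Most cells of each library carried the markers of the sorted type. AT1-like clusters gave 2849 cells at P3, or 90.5% (89.4 to 91.5), 2652 cells at P15, or 90.2% (89.1 to 91.3), and 1223 cells at P60, or 91.5% (89.8 to 92.9), and AT2-like clusters gave 2029 cells of the AT2 library, or 96.9% (96.1 to 97.6). These shares are set by the sort gates. The remaining clusters at P3 were ciliated and club-like (142 cells), AT2-like (65 cells) and endothelial and fibroblast-like (50 cells). At P15 they were fibroblast and pericyte or smooth muscle-like (110 cells), mixed AT2, ciliated and club-like (63 cells), immune-like (54 cells) and endothelial-like (42 cells), and at P60 they were AT2 and immune-like (53 cells) and endothelial-like (42 cells). Among the clusters within the AT1-like class, a P3 cluster of 666 cells was led by the immediate early genes Atf3, Fosb, Nr4a1, Fos and Jun, and several P15 and P60 clusters were led by Neat1 and Lars2. In the AT2 library a cluster of 531 cells was led by Fos, Fosb, Dusp1 and Egr1. A UMI of the club cell gene Scgb1a1 was found in 99.5, 71 and 96.4% of AT1-like cells at P3, P15 and P60 and in 92.5% of AT2-like cells, at 1026, 274, 1069 and 2074 CPM, that is, counts scaled to the total UMIs of the class in its library. In the other cells of the 4 libraries it read 23385, 42888, 1251 and 34848 CPM.

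6 genes were followed in every comparison, each placed on the mm10 (GRCm38) assembly by its protein-coding gene annotation. Ager, the receptor for advanced glycation end products, lies on chromosome 17 from 34597862 to 34600936. The water channel gene Aqp5 lies on chromosome 15 from 99590782 to 99594829, and Igfbp2, which encodes an insulin-like growth factor binding protein, on chromosome 1 from 72824503 to 72852474, all on the plus strand. On the minus strand lie Hopx, a homeodomain-only protein gene, on chromosome 5 from 77086988 to 77115121, Pdpn, the podoplanin gene, on chromosome 4 from 143267431 to 143299564, and Sftpc, the surfactant protein C gene, on chromosome 14 from 70520949 to 70524081. The 3' chemistry counts UMIs near the transcript ends, so the values are of genes and not of exons.

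**Figure D1:**
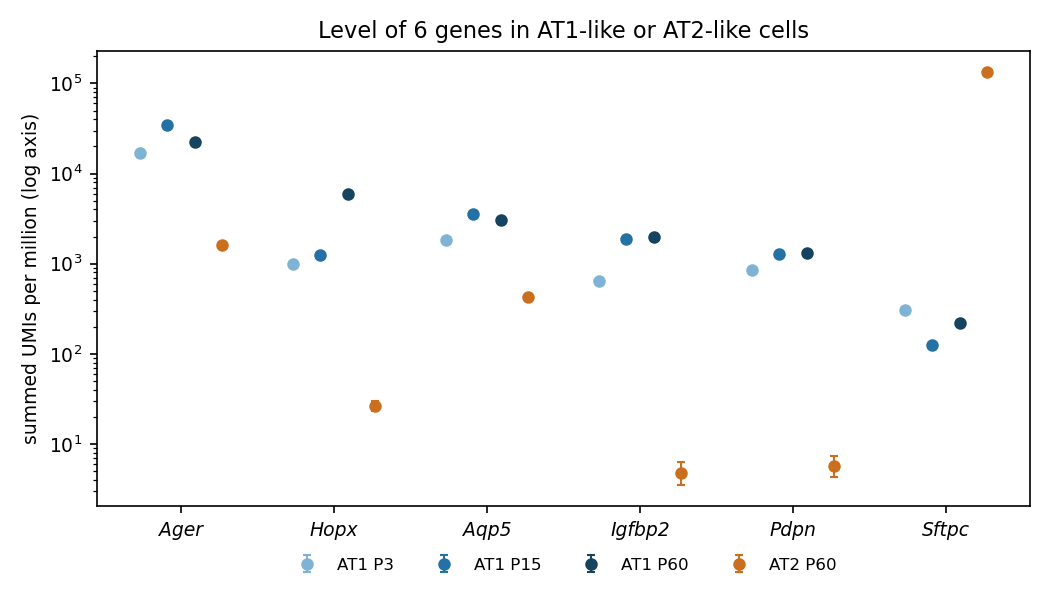
Summed UMIs as CPM (log axis) of 6 genes in AT1-like cells at P3, P15 and P60 and in AT2-like cells at P60, each point a single library with an exact 95% Poisson interval that is mostly smaller than the point. Hopx read 985, 1250 and 5918 at the 3 ages and 26.2 in AT2-like cells, and Igfbp2 read 647, 1875, 1993 and 4.7.

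The widest age span, P60 against P3, asks how AT1 cells differ between the newborn and the adult lung. The largest ratio upward was that of Cyp2b10, a cytochrome P450 gene, at 1724 CPM at P60 and 15.8 at P3, 109-fold higher (98.3 to 122), followed by a further P450 gene, Cyp4b1, at 58.3-fold (53.5 to 63.6), and Tm4sf1, a membrane protein gene, at 56.8-fold (48 to 67.7). The transcription factor gene Cebpb was 30.7-fold higher (26 to 36.3), Igfbp6 24.8-fold (23.8 to 25.9) and Ankrd1 18.4-fold (16.2 to 21.1). The tight junction gene Cldn3 was 219-fold lower at P60 (140 to 363), at 2.79 against 611 CPM. Msln, the mesothelin gene, was 88.1-fold lower (66.2 to 120), the water channel gene Aqp1 73.4-fold (60.8 to 89.5), the surfactant-associated gene Sfta2 48.2-fold (34.9 to 68.6) and the actin-binding thymosin gene Tmsb10 24.4-fold (22.9 to 25.9). Msln is also a mesothelial marker, and at P3 it read 609 CPM in AT1-like cells and 149 in the other cells of that library.

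AT1 identity genes were higher at P60 as a group, with 10 of 30 measured members at least 2-fold higher, 0 at least 2-fold lower and a median log2 ratio of 0.67, at percentile 100 of the random lists. Hopx was 6.01-fold higher (5.91 to 6.11), Igfbp2 3.08-fold (3.01 to 3.15), Aqp5 1.68-fold (1.66 to 1.71), Pdpn 1.53-fold (1.5 to 1.57) and Ager 1.32-fold (1.31 to 1.33). Hopx and Pdpn were part of the sort gate at each age. The insulin-like growth factor axis had 5 of 11 members higher and 1 lower (median 0.67, percentile 97.4), among them Igf2r at 4.09-fold (3.62 to 4.62), and the caveola genes had 3 of 8 higher and 0 lower (median 0.82, percentile 99.5), with Cav2 at 2.34-fold (2.26 to 2.41) and Cav1 at 2.01-fold (1.95 to 2.06). Antigen presentation and interferon genes had 13 of 23 higher and 2 lower (median 1.05, percentile 100). B2m, the light chain of class I molecules, was 4.87-fold higher (4.71 to 5.03) and Ifit1 9.69-fold (7.85 to 12), while Ifitm2 was 3.58-fold lower (3.04 to 4.24). MHC class II genes had a median of 1.65 (percentile 99.7), but of its 6 measured members only Cd74 reached 20 CPM, at 1.34-fold higher (1.22 to 1.48). Immune cell genes were also higher in these cells, with Tyrobp at 1.1 CPM at P3 and 13.1 at P60 and Cd52 at 0.22 and 3.82. H2-Aa and Cd74 were among the leading genes of the P60 AT2 and immune-like cluster. Targets of the YAP and TAZ coactivators had 6 of 17 higher and 2 lower (median 0.37, percentile 90.2), with Ankrd1 highest and Wwc1 at 2.65-fold (2.54 to 2.77). Antioxidant genes had 6 of 23 higher and 4 lower (median 0.43, percentile 94.4), with the peroxiredoxin gene Prdx6 at 2.42-fold (2.39 to 2.45) and the metallothionein gene Mt1 14-fold lower (10.3 to 19.4).

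The lists of perinatal regulators, TGF-beta and BMP response, imprinted growth network, immediate early genes and ribosomal protein genes had medians below 0 at P60 over P3. None of 10 measured perinatal regulators was 2-fold higher and 6 were lower (median -1.30, percentile 0), including Marcks at 36.1-fold (20.6 to 70) and Bex4 at 18.9-fold (16.2 to 22.1). The TGF-beta and BMP response list had 9 of 19 lower and 4 higher (median -0.98, percentile 0). Its inhibitor of differentiation genes parted, with Id1 14.4-fold lower (12.6 to 16.6), Id3 5.06-fold lower (4.8 to 5.34) and Id4 3.99-fold higher (3.3 to 4.85). The imprinted growth network had 3 of 8 lower and 1 higher (median -0.65, percentile 0.14), with the cell cycle inhibitor gene Cdkn1c at 0.441 against 43.5 CPM, 98.7-fold lower on few P60 counts (33.7 to 479), and Grb10 5.52-fold lower (4.45 to 6.93). Meg3, a maternally expressed long noncoding RNA at 964 CPM at P3, was not listed at P60, nor was Fstl1 at 132 CPM, so no fold is given for these. Immediate early and dissociation response genes had 17 of 23 lower and 2 higher (median -1.67, percentile 0), with Fos at 22.8-fold (21.2 to 24.6), Nr4a1 at 30.4-fold (19.9 to 49.3) and Atf3 at 16.2-fold (13.9 to 19). Cebpb, a member of this list too, went the other way, at 30.7-fold higher (26 to 36.3). Ribosomal protein genes had 86 of 99 lower and 0 higher (median -2.10, percentile 0), with Rps12 at 10.3-fold (9.77 to 10.8) and Rps24 at 9.18-fold (8.8 to 9.59), and took 4.6% of UMIs at P60 against 19.4% at P3. The nuclear RNA Malat1 moved the other way, from 4.27% of UMIs at P3 to 15.9% at P60. Genes of the mitochondrial genome had 3 of 13 higher and 0 lower (median 0.51, percentile 97.8).

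Of the genes listed in both libraries, 11378, 3457 passed the expression minimum, and 455 were at least 2-fold higher at P60 and 331 lower, with 98 and 145 at least 4-fold. AT2 identity genes, mostly at low levels in these cells, had 12 of 28 lower and 5 higher (median -0.39, percentile 0.05), and Sftpc was 1.41-fold lower (1.33 to 1.49), a direction that turned to a log2 ratio of 0.21 when cells with 3 or more AT2 markers were left out. The split of higher and lower genes moved with the scaling, to 315 and 422 with a trimmed mean of log ratios, 316 and 511 when ribosomal protein, mitochondrial and haemoglobin genes were left out of the total, and 717 and 288 without Malat1 in it. The medians of 12 further lists, among them basement membrane (0.05), ion and water transport (0.03), cell cycle (-0.10), lung transcription factors (-0.09) and actin cytoskeleton (-0.17), lay so near 0 that their sign depended on that choice.

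P15 against P3 covers the time when alveoli form in the mouse lung. Cyp2b10 was 73.3-fold higher at P15 (66 to 81.6) and Cyp4b1 23.6-fold (21.6 to 25.7), so both P450 genes stood high by that age. Interferon-response genes were among the largest ratios, with Ifit1 at 20.8-fold (17.2 to 25.2), Ifit3 at 10.7-fold (10 to 11.4) and Isg15 at 9.95-fold (8.84 to 11.2). Glucocorticoid-response genes were higher too, with the kinase gene Sgk1 at 11.2-fold (10.7 to 11.8), Tsc22d3 at 7.79-fold (7.51 to 8.08) and Klf15 at 7.2-fold (6.46 to 8.03). Among the genes lower at P15, Cldn3 was 21.7-fold lower (19.6 to 24), Meg3 9.66-fold (9.15 to 10.2) and the morphogen gene Shh 6.8-fold (6.08 to 7.62).

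AT1 identity genes had 6 of 30 higher and 0 lower (median 0.69, percentile 100). Igfbp2 was 2.9-fold higher (2.84 to 2.96), Rtkn2 2.82-fold (2.76 to 2.89), Ager 2.09-fold (2.08 to 2.1), Aqp5 1.99-fold (1.96 to 2.01), Pdpn 1.51-fold (1.47 to 1.54) and Hopx 1.27-fold (1.24 to 1.29), while Akap5 was 1.72-fold lower (1.68 to 1.75). In the insulin-like growth factor axis 6 of 12 were higher and 1 lower (median 1.05, percentile 100), with Igfbp7 at 3.24-fold (3.21 to 3.28) and the protease gene Htra1 at 2.86-fold (2.69 to 3.03). Basement membrane genes had 5 of 23 higher and 0 lower (median 0.62, percentile 99.9), including the collagen IV genes Col4a5 at 2.58-fold (2.48 to 2.68) and Col4a2 at 2.38-fold (2.33 to 2.44). The glucocorticoid and circadian list had 9 of 18 higher and 1 lower (median 0.69, percentile 100), with Fkbp5 at 8.17-fold (6.18 to 10.9) and the clock gene Nr1d1 2.27-fold lower (1.87 to 2.78). Antigen presentation and interferon genes had 11 of 23 higher and 0 lower (median 0.96, percentile 100), caveola genes 1 of 8 higher and 0 lower (median 0.77, percentile 99.2) with Cav1 at 4.06-fold (3.98 to 4.14), and ion and water transport 3 of 19 higher and 4 lower (median 0.34, percentile 93.8), with the sodium pump gene Atp1b1 at 2.58-fold (2.51 to 2.66). Lysosome genes had 4 of 20 higher and 3 lower (median 0.38, percentile 97.3).

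Perinatal regulators were lower at P15, 10 of 14 with 0 higher (median -1.54, percentile 0), led by Mycn at 11.3-fold (8.94 to 14.4) and Marcks at 11-fold (8.75 to 13.9). AT2 identity genes had 13 of 28 lower and 1 higher (median -0.90, percentile 0), with Sftpc 2.48-fold lower (2.35 to 2.62) and Sfta2 8.56-fold (7.76 to 9.47), and innate defence genes had 7 of 11 lower and 0 higher (median -1.13, percentile 0.025). At the same age the club cell gene Scgb1a1 was also low, at 274 CPM against 1026 at P3. Secreted growth factors and guidance cues had 7 of 25 lower and 2 higher (median -0.33, percentile 0.1), lung transcription factors 3 of 17 lower and 0 higher (median -0.35, percentile 1.58) with Foxp2 at 2.12-fold (1.93 to 2.32), and the TGF-beta and BMP response 9 of 19 lower and 2 higher (median -0.67, percentile 0), which became 0.09 when all cells of the libraries were summed. Immediate early genes had 10 of 23 lower and 2 higher (median -0.67, percentile 0), with Atf3 at 7.52-fold (6.96 to 8.12) and Egr1 at 5.65-fold (5.15 to 6.2), while Klf2 was 4.1-fold higher (3.86 to 4.36). Ribosomal protein genes had 87 of 101 lower and 0 higher (median -1.54, percentile 0), and their share of UMIs was 7.03% at P15. Malat1 took 6.68% there.

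Of 12547 genes listed in both libraries, 3283 passed the minimum, and 302 were at least 2-fold higher and 218 lower, with 46 and 54 at least 4-fold. That split became 222 and 254 with median-of-ratios size factors and 198 and 338 without ribosomal protein, mitochondrial and haemoglobin genes in the total. Psca at 285 and Cnfn at 187 CPM at P3 were not listed at P15. However, 4 cells held 89.9 and 87% of these UMIs and without them the levels were 28.9 and 24.4 CPM.

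The step from P15 to P60 compares AT1 cells of the alveolar stage with adult ones, and it held fewer large ratios. Hopx was 4.73-fold higher at P60 (4.65 to 4.82), Igfbp6 9.18-fold (8.87 to 9.5), Cebpb 9.35-fold (8.28 to 10.6) and the angiogenic factor gene Vegfa 2.34-fold (2.29 to 2.4). Msln was 53.5-fold lower (40.2 to 72.9), Aqp1 34.5-fold (28.6 to 42.1), Tmsb10 11.2-fold (10.5 to 11.9), the cathepsin gene Ctsh 7.16-fold (6.72 to 7.64) and Tsc22d3 6.2-fold (5.86 to 6.56). Msln read 370 CPM in AT1-like cells at P15 and 369 in the other cells of that library. Igfbp2 read 1875 and 1993 CPM, a ratio of 1.06 (1.04 to 1.09) that turned to a log2 ratio of -0.03 under a trimmed mean, and Pdpn a ratio of 1.02 (0.993 to 1.05). Ager was 1.58-fold lower at P60 (1.57 to 1.59), Aqp5 1.18-fold lower (1.16 to 1.2) and Sftpc 1.77-fold higher (1.65 to 1.89).

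The AT1 identity list had 3 of 30 members higher, 1 lower and a median of 0.04 (percentile 99.7), where the random lists lay around -0.30. The median became -0.08 under the trimmed mean. YAP and TAZ targets had 2 of 16 higher and 0 lower (median 0.26, percentile 98.1), including Ankrd1 at 3.35-fold (3.08 to 3.64). Innate defence genes had 9 of 13 higher and 2 lower (median 1.81, percentile 100), with Lyz2 at 5.1-fold (4.14 to 6.32) and Sftpa1 at 4.53-fold (3.74 to 5.5), but these levels were low, at 47 and 51.6 CPM, in a library where Scgb1a1 read 1069 CPM against 274 at P15, and Sftpd was 9.13-fold lower (7.07 to 12). S100a8, a neutrophil gene, was 33.1-fold higher (20.6 to 56.6) at 43.2 CPM and also led the AT2 and immune-like cluster of that library. Several lists were lower at P60 than at P15. Basement membrane genes had 7 of 23 lower and 0 higher (median -0.67, percentile 0.015), with Col4a5 at 2.59-fold (2.44 to 2.75) and Lama5 at 2.58-fold (2.31 to 2.88). The glucocorticoid and circadian list had 7 of 17 lower and 1 higher (median -0.80, percentile 0), with Nr1d1 5.9-fold higher (4.82 to 7.27). For this list age cannot be told apart from library or the handling of the lungs on the day, at either age step. Ion and water transport had 6 of 18 lower and 0 higher (median -0.58, percentile 0.04), with Atp1b1 at 3.96-fold (3.75 to 4.18). Antigen presentation and interferon genes had 6 of 23 lower and 1 higher (median -0.37, percentile 0.09), with Isg15 at 3.9-fold (3.41 to 4.47). Perinatal regulators (5 of 10 lower and 1 higher, median -0.78, percentile 0), immediate early genes (15 of 23 lower and 1 higher, median -1.24, percentile 0) and ribosomal protein genes (6 of 99 lower and 3 higher, median -0.55, percentile 0) were lower again, while the Malat1 share went from 6.68 to 15.9% of UMIs.

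Of 11320 genes listed in both, 3421 passed the minimum, and 136 were at least 2-fold higher and 148 lower, with 31 and 32 at least 4-fold. The split became 101 and 200 with a trimmed mean and 249 and 114 without Malat1 in the total. Zc3hc1 at 19.3-fold higher (17 to 22.1), Lars2, Wdr89 and AY036118 also stood among the largest ratios, but whether 1 gene annotation served all libraries is not given in the sources used here, so these values and that of Rnaset2b are uncertain. Rnaset2b, Eif3j1 and the histone gene Hist1h2bc also have close copies elsewhere in the genome, which makes their values uncertain.

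**Figure D2:**
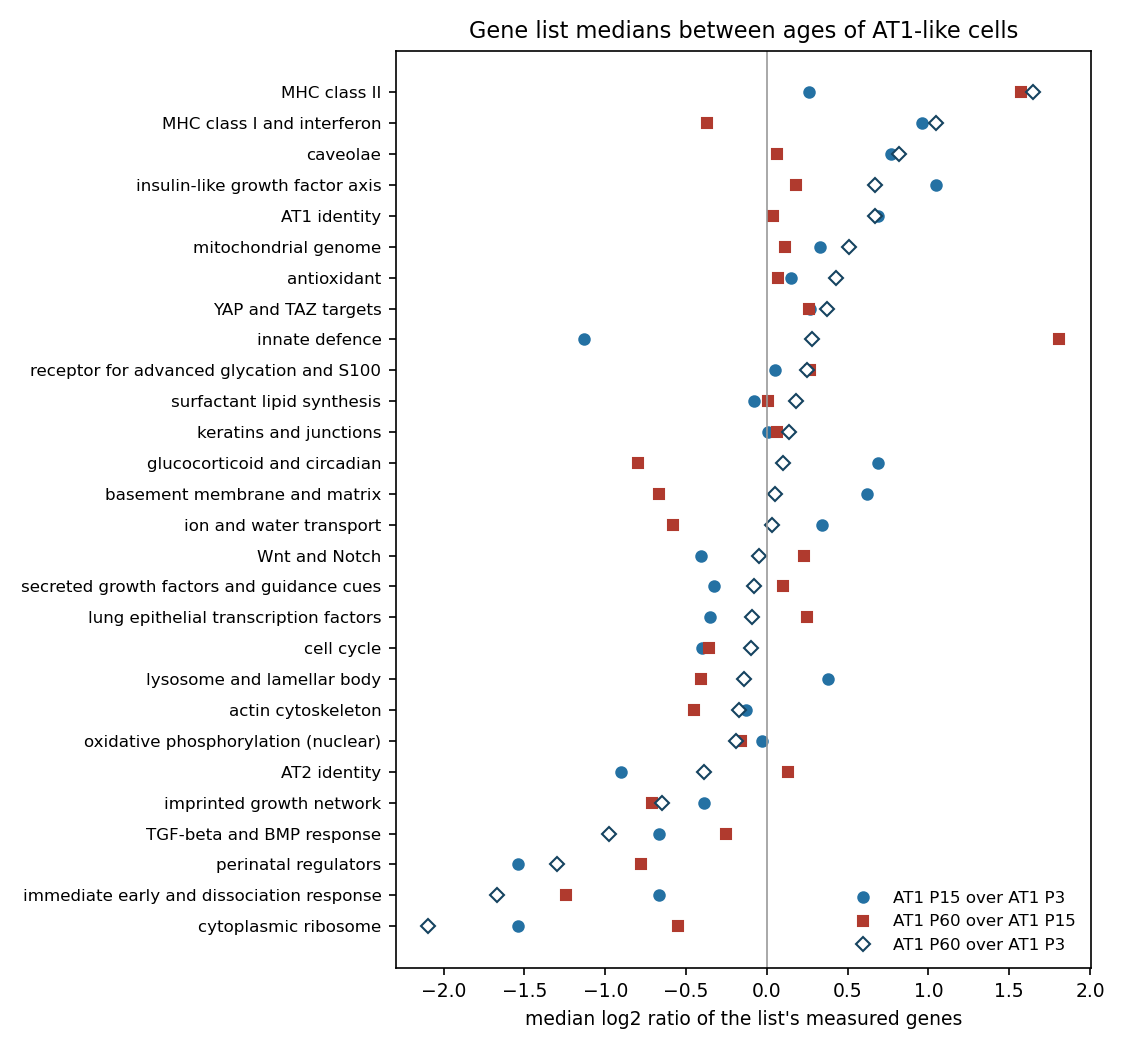
Median log2 ratio of the measured genes of each fixed list in AT1-like cells, with circles for P15 over P3, squares for P60 over P15 and open diamonds for P60 over P3. Ribosomal protein genes lay at -1.54, -0.55 and -2.10 and antigen presentation and interferon genes at 0.96, -0.37 and 1.05, while lists near 0, such as AT1 identity for P60 over P15 at 0.04 and keratins and junctions, changed sign under another scaling.

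AT2 cells against AT1 cells at P60 set both alveolar types side by side at the adult age. AT2-like cells were 1412-fold higher in the fatty acid desaturase gene Scd1 (941 to 2228), 1264-fold in the phosphate transporter gene Slc34a2 (856 to 1953), 983-fold in the lamellar body gene Lamp3 (534 to 2050), 739-fold in Sftpa1 (666 to 823) and 642-fold in Sftpd (501 to 838). Cebpa, which encodes a transcription factor, was 1113-fold higher on few AT1 counts (308 to 9192). In AT1-like cells Igfbp2 was 424-fold higher (320 to 576), Rtkn2 475-fold (326 to 721), Sdpr 237-fold (181 to 317) and Cav1 220-fold (170 to 289). Several genes of AT1-like cells were listed at 0 in the AT2 library, led by Spock2 at 802, Sema3e at 477, Bdnf at 376 and Akap2 at 321 CPM, and no fold is given because such zeros may be filled in. Sftpc was 617-fold higher in AT2-like cells (587 to 650) and Hopx and Pdpn were 226-fold (200 to 255) and 229-fold (177 to 302) lower, but all 3 belong to the reporters or the antibody that defined the gates. The AT2-like levels of Igfbp2 and Pdpn rest on 48 and 58 UMIs in 21 and 22 cells. Ager was 13.9-fold lower in AT2-like cells (13.7 to 14.1) and Aqp5 7.1-fold lower (6.88 to 7.34), smaller ratios than those of the other 4 genes. An Ager UMI was found in 91.1% of AT2-like cells after thinning to 2000 UMIs (89.8 to 92.4) and in 97.8% without. Ager stood at 7.19% and Aqp5 at 14.1% of the AT1-like level, and Hopx, Pdpn and Igfbp2 at 0.443, 0.436 and 0.236%.

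The identity lists parted almost completely, with 30 of 30 AT1 genes at least 2-fold lower in AT2-like cells (median -5.15, percentile 0) and 29 of 30 AT2 genes higher (median 8.88, percentile 100). The exception, the lung transcription factor gene Nkx2-1, was 1.31-fold lower (1.25 to 1.38), a direction that turned under scalings that shift the log2 ratios by 0.72 and 0.65. The 30 AT1 genes take in Spock2 and Sema3e, which were listed at 0 in AT2 cells and entered at the floor. Both identity lists hold all the markers that named the AT1-like and AT2-like clusters, and genes of the sort gates. Part of this parting was therefore set by how the classes were made, and its percentiles are no independent support. Further lists below share some of these markers. Basement membrane holds Col4a3 and Spock2, the S100 list Ager and S100g, and lung transcription factors Hopx and Etv5. Innate defence holds Hc, Lyz2, Sftpa1 and Sftpd among others, and surfactant lipid synthesis Abca3, Scd1 and Fabp5. Their percentiles are thus not fully independent of the class naming either. Several further lists had more members lower than higher in AT2-like cells. Their counts take in genes listed at 0 in AT2 cells at the floor, such as Sema3a, Sema3e and Tgfb2 among the secreted factors. Caveola genes had 7 of 8 lower and 0 higher (median -4.96, percentile 0), basement membrane genes 20 of 23 lower and 1 higher (median -3.95, percentile 0) with Col4a3 at 130-fold (104 to 165), and secreted growth factors and guidance cues 16 of 21 lower and 1 higher (median -4.08, percentile 0), where Tgfb2 at 163 CPM in AT1-like cells was listed at 0 in AT2 cells. YAP and TAZ targets had 14 of 17 lower and 1 higher (median -3.13, percentile 0), with Ankrd1 at 251-fold (132 to 549), keratins and junctions 13 of 19 lower and 2 higher (median -1.97, percentile 0.05), with Krt7 at 33.1-fold (30.6 to 35.9) and Cldn3 180-fold higher (115 to 299), and the insulin-like growth factor axis 7 of 10 lower and 1 higher (median -3.71, percentile 0.01), with Igf1r at 33.3-fold (25.3 to 44.6) and Irs2 7.31-fold higher (5.38 to 10.2). The S100 list had 9 of 15 lower and 2 higher (median -1.46, percentile 1.55), with S100a6 at 37.7-fold (35.5 to 40.1) and the calcium-binding gene S100g 471-fold higher (348 to 653), and the TGF-beta and BMP response 9 of 18 lower and 4 higher (median -1.28, percentile 1.5).

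Genes of surfactant, innate defence and MHC class II were higher in AT2-like cells, where the first 2 of these groups hold markers that named the AT2-like clusters. Innate defence had 13 of 15 higher and 2 lower (median 8.54, percentile 100), with Hc, complement component 5, at 956-fold on few AT1 counts (327 to 4635). Surfactant lipid synthesis had 19 of 25 higher and 3 lower (median 3.02, percentile 100), with the fatty acid binding protein gene Fabp5 at 591-fold (383 to 969) and Scd2 3.44-fold lower (3.34 to 3.55). All 6 measured MHC class II genes were higher (median 5.88, percentile 100), among them H2-Aa at 132-fold (100 to 177) and H2-Ab1 at 83.8-fold (65.7 to 109), while antigen presentation and interferon genes had 11 of 23 lower and 2 higher (median -0.86, percentile 17.7). Antioxidant genes had 8 of 24 higher and 4 lower (median 0.79, percentile 100), with Mt1 at 37.6-fold (27.8 to 52.1). Ion and water transport parted, with 6 of 17 higher and 8 lower (median 0.55, percentile 99.5). The potassium channel gene Kcnj15 was 533-fold higher on few AT1 counts (147 to 4404), whereas the sodium channel gene Scnn1g was 170-fold lower (122 to 246). Lung transcription factors had 5 of 15 higher and 2 lower (median 0.34, percentile 99.3), with Etv5 at 344-fold (192 to 690). Ribosomal protein genes had 74 of 98 higher and 2 lower (median 1.45, percentile 100) and the mitochondrial genome 7 of 13 higher and 0 lower (median 1.07, percentile 96.1), beside a Malat1 share of 4.04% in AT2-like and 15.9% in AT1-like cells. The highest mitochondrial share of a cell was 9.94% in the P60 AT1 library and 15% in the AT2 library. Unlike filters before deposit may therefore bear on the mitochondrial list, which was not tested. Immediate early genes had 9 of 22 higher and 6 lower (median 0.56, percentile 99.9), which became -0.24 when all cells were summed.

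Of 11561 genes listed in both, 3495 passed the minimum, and 464 were at least 2-fold higher in AT2-like cells and 1415 lower, or 1364 lower without the genes at 0, with 231 and 654 at least 4-fold. Sftpc alone took 13.6% of AT2-like UMIs, Sftpa1 3.81% and Lyz2 2.74%, and the split became 759 and 792 with median-of-ratios size factors and 733 and 823 with a trimmed mean. Cell type, library and dissociation enzymes differed together in this comparison.

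**Figure D3:**
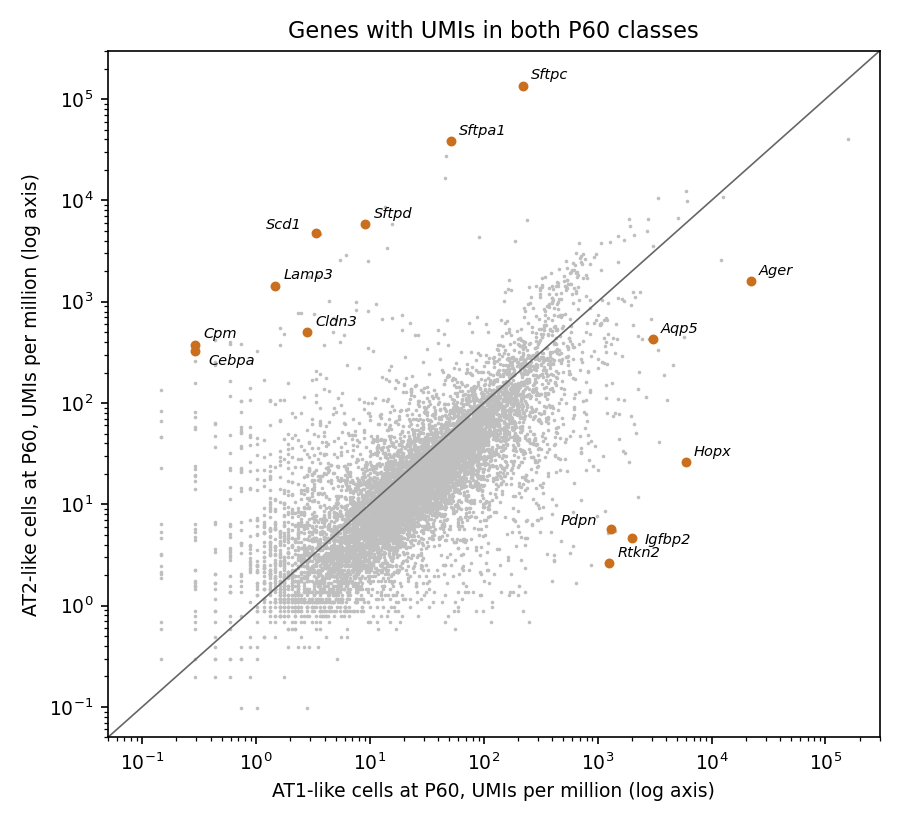
CPM of each gene in AT1-like cells (horizontal, log axis) and AT2-like cells (vertical, log axis) at P60, each point a gene with UMIs in both and the line marking equal values. Named genes are orange, and Sftpc lies 617-fold above the line while Igfbp2 lies 424-fold and Ager 13.9-fold below it.

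Igfbp2 is known from the group's work as a gene that splits AT1 cells, so the share of AT1-like cells with an Igfbp2 UMI was followed over age. After each cell was thinned to 2000 UMIs the share was 48.7% at P3 (46.9 to 50.6), 79.6% at P15 (78 to 81.2) and 89.3% at P60 (87.3 to 91), and without thinning it was 72, 86.9 and 94.8%. In AT2-like cells, which should lack the gene, it was 0.654% after thinning (0.349 to 1.12) and 1.03% without. Cells outside the AT1-like class of the same AT1 libraries gave 24.7% (19.9 to 29.9), 22.8% (17.9 to 28.4) and 39.2% (28.4 to 50.9) after thinning and 58.7, 36.8 and 48.2% without. These cells include 43, 19 and 19 cells of AT1-like clusters that were set aside for markers of another lineage and may hold Igfbp2 of AT1 cells. Part of the UMIs in AT1-like cells can be background, but these shares do not measure how much. Median depths were 7290, 4937 and 5447 UMIs in AT1-like cells, 12395, 4878 and 3022 in the other cells of those libraries and 4901 in AT2-like cells. Thinning left out 0 cells at P3, 210 at P15 (7.92%), 122 at P60 (9.98%) and 42 AT2-like cells (2.07%).

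**Figure D4:**
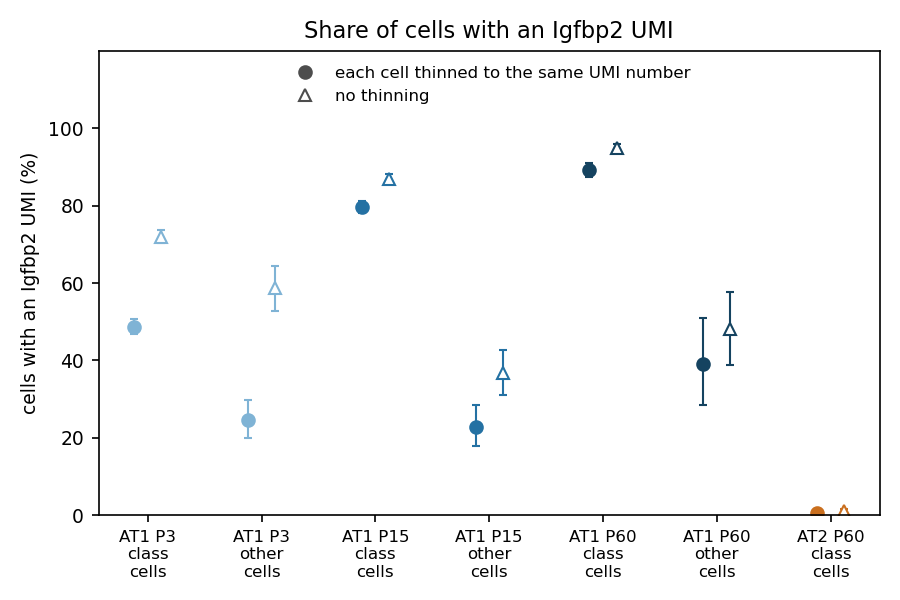
Percent of cells with an Igfbp2 UMI in AT1-like or AT2-like cells (class cells) and in the remaining cells of the AT1 libraries (other cells), with filled circles after thinning each cell to 2000 UMIs and open triangles without thinning, and bars for exact 95% binomial intervals. The thinned share in AT1-like cells was 48.7, 79.6 and 89.3% at P3, P15 and P60 and 0.654% in AT2-like cells.

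Within each AT1 library, cells with an Igfbp2 UMI were compared with cells without, to ask which other genes go with it. At P3, 1388 cells with a UMI and 1461 without were close in most genes, since 1 of 2934 genes was at least 2-fold higher with Igfbp2 and 4 were lower. Before thinning, 798, 348 and 63 AT1-like cells lacked an Igfbp2 UMI at P3, P15 and P60, against 1461, 498 and 118 after it. Some cells counted as without therefore held Igfbp2, which can narrow the differences. An AT1-like P3 cluster of 616 cells was led by Igfbp2, with Ctgf, Plod2 and Pcolce also among its leading genes. Higher with Igfbp2 were the potassium channel subunit gene Kcne2 at 1.9-fold (1.58 to 2.3), the matricellular gene Ctgf at 1.67-fold (1.53 to 1.83) and the collagen-modifying gene Plod2 at 1.64-fold (1.36 to 1.98). Lower with Igfbp2 were Igfbp6 at 1.95-fold (1.65 to 2.3), Sepp1 at 1.69-fold (1.44 to 1.99), Cldn3 at 1.49-fold (1.39 to 1.59) and Sftpc at 1.3-fold (1.18 to 1.44). Without thinning, 5 cells held 19.7% of the Sftpc UMIs of the P3 class. The Sftpc ratio was not taken without these cells, so it may rest on them. Psca, Cnfn and Gsto1 were 8.74-fold (6.98 to 11.1), 7.74-fold (5.86 to 10.4) and 2.12-fold (1.85 to 2.42) lower, but 4 cells held 89.9, 87 and 56.5% of their UMIs and without these cells the folds were 0.963, 1.33 and 0.931. At P15, 1944 cells with a UMI and 498 without had 0 of 3223 genes higher and 7 lower. Higher with Igfbp2 were Gpm6a at 1.98-fold (1.61 to 2.46), Isg15 at 1.92-fold (1.51 to 2.47) and the neurotrophic factor gene Ndnf at 1.76-fold (1.59 to 1.96). Lower with Igfbp2 were Cldn3 at 7.33-fold (5.3 to 10.2), Acot1 at 2.91-fold (2.24 to 3.77), Sftpd at 2.64-fold (2.17 to 3.2), Nnat at 2.06-fold (1.77 to 2.39), Igfbp6 at 1.8-fold (1.62 to 2.01) and Id2 at 1.77-fold (1.47 to 2.13). Of these 6 genes, Cldn3, Acot1, Sftpd, Nnat and Id2 were 180, 43.2, 642, 2.61 and 13.2-fold higher in AT2-like than in AT1-like cells at P60, and Igfbp6 was 23.5-fold lower. Sftpc differed by 1.05-fold (0.865 to 1.28) in this split. Without thinning, a Cldn3 UMI was found in 7.47% of the AT1-like cells at P15, and 5 cells held 12.6% of the Cldn3 UMIs. At P60, 983 cells with a UMI faced 118 without, and 51 of 2326 genes were higher and 1 lower. These counts rest on few UMIs, such as 10 for Msl3l2 in the cells without. The cells with held 1961890 UMIs after thinning and the cells without 236000. The UMI minimum in the higher part therefore asked for a higher CPM of genes lower with Igfbp2 than of genes higher with it. For this reason, and because counting error is wide at so few UMIs, the split of 51 and 1 cannot show a direction. Stag2 was 2-fold lower with Igfbp2 (1.33 to 2.95) and Tmsb10 1.93-fold (1.46 to 2.52). Ager was 1.15-fold higher (1.12 to 1.19), against 1.09-fold (1.07 to 1.1) at P15 and a ratio of 1 (0.992 to 1.02) at P3. At P3 Hopx and Aqp5 were 1.05-fold (0.996 to 1.11) and 1.02-fold (0.985 to 1.06) lower with Igfbp2, intervals that include 1. Pdpn was 1.13-fold higher (1.06 to 1.19). A cell without a UMI may still express the gene.

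Cells with UMIs of at least 2 of 9 cell cycle genes were not detected among AT1-like cells after thinning, with 0 of 2849 at P3, which allows a share of up to 0.105% by 3 counts of the total, and 0 of 2442 at P15, which allows up to 0.123%. The exact upper limits were 0.129 and 0.151%, and all of these limit cells with such UMIs at this depth, not cycling cells. Without thinning there was 1 such cell at each of these ages, 0.0351 and 0.0377%. The P3 library listed 8 of the 9 genes, the P15 library 9 and the P60 AT1 library 0, so no share is given at P60. The AT2 library listed only Mki67, with a UMI in 34 of 1987 thinned AT2-like cells (1.71%). With 1 gene listed the rule of 2 genes cannot be met, so this is not a share of cycling cells. Mki67 was also among the leading genes of the unnamed AT2 cluster of low UMI count. 0 of the 5 erythroid genes were measured in any comparison, and Hba-a1 read 3.52 CPM in AT1-like cells at P3.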

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

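The alternatives without Malat1 in the total, with cells of other lineages kept, without single clusters, without genes at 0 and without cells of 30 or more Psca UMIs were chosen only after the data had been seen, and the others had been planned. No paired analysis was possible because each group had 1 library. The number of genes at least 2-fold apart moved with the expression minimum, which admits more or fewer genes by construction. At 20 CPM it was 1283 for P60 over P3, 796 for P15 over P3, 502 for P60 over P15 and 3183 for AT2 over AT1, and at 200 CPM 332, 254, 99 and 617, against 786, 520, 284 and 1879 at 50 CPM. No other alternative moved these counts by over 1.5 times. The share of cells with an Igfbp2 UMI followed the depth it was read at. At P3 it was 33.8% at 1000 UMIs, 57.6% at 3000 and 72% without thinning, at P15 65.7, 85.8 and 86.9% and at P60 74.5, 95.3 and 94.8%. With 2 or more UMIs required it was 28.5, 64.7 and 74.6%, and over all cells 46.4, 74.1 and 85.9%. Requiring 1 cell cycle gene in place of 2 gave 0.878% of cells at P3 and 0.655% at P15, and the AT2-like share at Leiden resolution 1 was 95.9%. At that resolution a cluster of 45 cells of the AT2 library (2.15%) carried AT2 markers but was led by AT1 genes and stayed unnamed. Without thinning 22, 12 and 128 genes were 2-fold apart in the split by Igfbp2 at P3, P15 and P60, against 5, 7 and 52, and at P3 1 gene was left without the cells of 30 or more Psca UMIs.

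Where a direction turned, the cause was not tested. The log2 ratio of Sftpc at P60 over P3 was 0.21 without cells holding 3 or more AT2 markers, and that of Igfbp2 at P60 over P15 was -0.03 with a trimmed mean. In AT2 over AT1, Nkx2-1 turned to 0.32 with size factors and 0.26 with a trimmed mean, and Bmp4 to 0.55 and 0.49 under these, 0.06 without ribosomal protein, mitochondrial and haemoglobin genes and 0.04 after thinning. With cells of other lineages kept, Lyz2, S100a8 and S100a9 at P60 over P3 turned to -0.24, -0.83 and -0.12 and S100a9 in AT2 over AT1 to 0.12. Without Malat1, Ptrf at P60 over P3 turned to 0.04, and after thinning Pacsin3 at P60 over P15 turned to -0.14. Summed over all cells, Sftpa1, Cxcl15 and Gstm1 turned to -0.07, 0.10 and -0.21 at P60 over P3, Ifitm2 and Wfdc2 to 0.14 and -0.09 at P15 over P3, and Sftpb and Cd74 to -0.43 and 0.07 at P60 over P15. In the same sums the TGF-beta and BMP response at P15 over P3 had a median of 0.09, and perinatal regulators and immediate early genes in AT2 over AT1 -0.53 and -0.24. Oxidative phosphorylation genes in AT2 over AT1 went from 0.09 to -0.10 without Malat1. Of 5917 values under an alternative, taken over the genes with the largest ratios, the 6 genes followed throughout and the examples of each list, 4285 stayed within their counting interval, 1611 moved and 21 turned from a ratio whose interval left out 1. Of 364 list medians with size factors, all cells, no Malat1 or no genes at 0, 135 stayed and 225 moved, which takes in sign changes of lists inside the middle 95% of random lists, and 4 turned from outside it. Over all 4 scalings 39 of 448 list medians changed sign, 20 of them at P60 over P3, and 3 of the 39 were of lists outside that range. Scaling shifted all log2 ratios of a comparison alike, by -0.12 with size factors, -0.22 with a trimmed mean, -0.25 without ribosomal protein, mitochondrial and haemoglobin genes and 0.19 without Malat1 for P60 over P3. In that order the shifts were -0.13, -0.05, -0.21 and 0.04 for P15 over P3, 0.04, -0.12, -0.04 and 0.15 for P60 over P15, and 0.72, 0.65, 0.22 and -0.19 for AT2 over AT1. The share of higher genes among those 2-fold apart went from 57.9% to 42.7% with a trimmed mean, 38.2% without ribosomal protein genes and 71.3% without Malat1 for P60 over P3, from 58.1 to 46.6% with size factors and 36.9% without ribosomal protein genes for P15 over P3, from 47.9 to 33.6% with a trimmed mean and 68.6% without Malat1 for P60 over P15, and from 24.7 to 48.9% with size factors and 47.1% with a trimmed mean for AT2 over AT1.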

Other observations

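The tests on pseudogenes and both tests on free RNA were chosen only after the result they measure had been seen, and the others had been written down before. In these tests, ranges after list medians and after the ratio of Ager to other AT1 identity genes came from resampling the genes. Such ranges show the spread over genes treated as independent, although genes of a list may vary together, and are not counting intervals. Oxidative phosphorylation genes of the nucleus had a median log2 ratio of -0.19 over 84 measured genes in AT1-like cells at P60 against P3 (percentile 1.47), with 5 members at least 2-fold lower and 2 higher. Leaving Malat1 out of the totals shifts all ratios by 0.19, which brings this median to 0, so no direction is given for the list. Cox7a2l was 4.64-fold lower (4.34 to 4.97). In the surfactant lipid list at P60 over P3 the desaturase gene Scd2 was 3.85-fold higher (3.76 to 3.94) and Lpin2 4.44-fold (4.13 to 4.77), while Acot1 was 34.2-fold lower (23.6 to 51.5), and the list median of 0.18 turned to -0.04 under a trimmed mean. In AT2-like against AT1-like cells the heart-type subunit gene Cox6a2 was 61-fold higher (40.5 to 96.4) and the Wnt inhibitor gene Nkd1 66.5-fold (36 to 139). The glucocorticoid and circadian list had opposite members there, with Dbp 24.2-fold higher in AT2-like cells (16.3 to 37.5) and Sgk1 57.7-fold lower (42.3 to 80.7), and its median of -0.52 turned to 0.20 with size factors. 28 genes past the minimum were listed in the AT2 library alone, led by Nrn1 at 251, Lrp2 at 236 and Mlc1 at 181 CPM.

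Ribosomal protein genes were lower in AT1-like cells at P60 than at P3, with a median log2 ratio of -2.10. The larger Malat1 share at P60 was not enough as the whole cause. Leaving Malat1 out of both totals shifts every log2 ratio by only 0.19, a shift set by the Malat1 shares, to a median of -1.91 (-2.02 to -1.80). Reads going to listed pseudogenes were argued against by a ratio of 0.346 (0.341 to 0.351) of their summed CPM, 2852 at P60 and 8238 at P3, and 0.349 over the 55 listed in both. Pseudogenes not listed stay open, and a difference in gene annotation or gene filter between the libraries, which was not tested, would move this ratio. Damaged cells rich in nuclear RNA cannot be told apart from an age difference, because only 34 of 1223 P60 cells had a Malat1 share in the range of most P3 cells (1.78 to 8.03%), although the median in these was -1.55. An age difference in protein synthesis genes may also account for the pattern and was not tested, since age and library are the same here.

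Ager and Aqp5 UMIs were frequent in AT2-like cells, where 97.8% of cells had an Ager UMI and the levels were 7.19% (Ager) and 14.1% (Aqp5) of those in AT1-like cells. AT1 cells or doublets among the AT2-like cells could not hold most of them, since the 8.03% of cells with a UMI of Hopx, Pdpn or Igfbp2 held 11.2% of the Ager UMIs (10.7 to 11.7). Free RNA from AT1 cells cannot be told apart by the ratio of Ager to the median of 20 other AT1 identity genes, 2.77 (1.43 to 7.47), because those genes spread widely. Hopx, Pdpn and Igfbp2 stood at 0.443, 0.436 and 0.236%. The Ager ratio was 16.2 times (14.2 to 18.7) the highest of these, which argued against free RNA if free RNA keeps AT1 genes in 1 ratio. In the other cells of the P60 AT1 library Ager, Aqp5, Hopx, Pdpn and Igfbp2 stood at a like 28.2, 27.1, 25.6, 27 and 21.6% of the AT1-like level. Those cells include 19 cells of AT1-like clusters, so this likeness does not show how free RNA behaves. A candidate explanation that stays open is low expression of both genes in AT2 cells, which was not tested.

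Immediate early genes were lower in AT1-like cells at P60 than at P3, with a median log2 ratio of -1.67. A group of activated P3 cells in a single cluster was argued against as the whole cause, since without its 665 cells the median was -1.49 (-2.85 to -1.01). The Malat1 share was not enough either, since leaving Malat1 out of both totals shifts every log2 ratio by only 0.19, to a median of -1.49 (-3.04 to -1.11). That shift is set by the Malat1 shares and could not have brought the median near 0. Differences in the handling of the lungs on the day may be the cause as much as age, and neither was tested with 1 library per age.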
